A study of Oryza sativa with 36 samples.

How the data were processed

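The data were 36 tables of raw counts per gene locus, 1 per library, with 55986 loci each. Of these, 55801 had IDs that begin with the chromosome number and 185 lay on unanchored sequence and had no count in any library. According to the labels' protocols, rice was grown in calcined clay watered with a modified Kimura B nutrient solution, RNA of 3 independent plants was pooled per library, and libraries were made with a directional poly(A) RNA kit. Reads were aligned with STAR and counted with featureCounts 1.6.4 against the genome build IRGSP-1.0, per the submitters' processing notes. The strand setting of the counting, the gene annotation and any read filters are not given in the sources used here, so reads of overlapping loci, antisense loci and near-identical copies may be split or shared. The values are raw counts as the authors deposited them, whole numbers whose totals differ between libraries. No 2 libraries held identical counts, and replicate pairs differed by at least 4.90 times the chi-square per degree of freedom that sampling alone gives. Every library was counted as 1 replicate, although these values do not show that the libraries came from separate plants.

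Libraries were grouped by the accession, tissue and position in their titles into 12 groups of 3. The deposited column names carry 3 library codes: all KP leaf libraries and IR64 leaf position A shared 1 code, IR64 leaf positions B and C and KP root tip positions A and B another, and KP root tip position C and all IR64 root tip libraries the last. The code was treated as a possible batch.

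Counts were tested in R 4.3.3 with edgeR 4.0.16. Loci were kept by edgeR's expression filter with the groups given, counts were scaled by TMM factors, and dispersions and quasi-likelihood fits were made with robust estimation. Position and accession were tested in a model of the 6 groups of a tissue (20848 loci in leaf, 21816 in root tip), and tissue in a model of all 12 groups (24404 loci). Position was an F test of the 3 positions within an accession and tissue, and accession and tissue comparisons averaged the 3 positions. The threshold was a Benjamini-Hochberg adjusted p of 0.05. CPM values were scaled by the same factors, within the tissue for position and accession and over both tissues for the tissue comparison, and log2 CPM used a prior count of 2. Standard errors of log2 fold changes come from the quasi-likelihood fit. Shares of loci with 95% intervals inside -1 to 1 on the log2 scale used the same errors. The totals per library, between 18418000 and 31886800 counts rounded to 6 digits, set the counting error of each value. Reads carry no molecular identifiers, so intervals cover the spread between libraries and not amplification.

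The comparisons, tests and alternatives were set before the data were examined, with exceptions named where they occur. The rule for named loci asked for gene symbols or descriptions. None of the 55986 IDs matched the gene table used here (0 matches), and the files do not pair IDs with names, so at most 2 higher and 2 lower loci per comparison are given by ID: for accessions the largest log2 changes among loci past the threshold with a mean log2 CPM of at least 3 and no overlap of the 9 and 9 libraries, and for positions and tissues the smallest adjusted p. Of the position loci, higher or lower refers to position C against A. The planned tests of 25 gene lists and 4 named root and stature genes could not be run for the same reason. The 2 digits after the species letters of an ID were read as its chromosome.

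Alternatives were DESeq2 1.42.0 (its size factors in the edgeR fit, and its own Wald or likelihood ratio test), limma-voom (limma 3.58.1), no expression filter, a replicate block, each library left out, only the 9 libraries of an accession and tissue, a 2-fold threshold, accession tests within 1 library code and with the code as a term. Chosen after seeing the data were fits without 3 IR64 pools, counts thinned to the smallest library, fits without the 50 most abundant leaf loci, the position by tissue test, models of tissue and of the tissue by accession difference with the library code as a term, other groupings with the spread of 9 libraries, and the loci read in some pools. The fits were tested on simulated counts drawn with the means and spreads of these libraries and 200 changed loci. Each locus was drawn independently, while in the real libraries deviations were shared between loci. Far fewer loci changed than were called between accessions or tissues. The shares of false calls and recovered changes therefore describe the simulated counts and may not hold for the data. With a spread shared by both accessions, the share of false calls between positions was 17.4% in KP leaf, 9.82% in IR64 leaf, 0% in KP root tip and 37.5% in IR64 root tip, and with the 9 libraries alone it was 6.73%, 10.7%, 7.74% and 6.02%. In accession comparisons 79.1% of 2-fold changes were recovered in leaf and 86.6% in root tip, with 3.73% and 2.98% false calls. For tissue they were 71.6% in KP and 77.6% in IR64, with 3.21% and 1.29% false calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.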

Results

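Polyadenylated RNA was counted per gene locus in 36 libraries of rice, Oryza sativa. The libraries covered 2 accessions, IR64, a widely grown semi-dwarf indica variety, and Kinandang Patong (KP), an upland variety with deep roots. Leaves and the tips of all crown roots, the roots that arise from the stem base, were sampled after 3 weeks at 3 positions (A, B and C) in a growth chamber, without drought. Each of the 12 combinations of accession, tissue and position had 3 libraries, and each library held RNA pooled in equal amounts from 3 plants. The labels do not say whether the 3 libraries of a group came from separate sets of plants, so the p-values measure the spread between these libraries. The deposited counts summed to between 18418000 and 28856200 per leaf library (n = 18) and between 20224900 and 31886800 per root tip library (n = 18), totals rounded to 6 digits. Between 18442 and 19670 loci reached 10 counts in a leaf library, and between 19382 and 20707 in a root tip library. The 10 most abundant loci took 12.1% ± 1.36 of the counts in KP leaf, 10.7% ± 0.762 in IR64 leaf, 3.24% ± 0.0759 in KP root tip and 2.75% ± 0.106 in IR64 root tip (SD, n = 9 each). The files give locus IDs without gene names, and none of the IDs occurred in the gene table used here, so loci are given by ID and none is assigned a function.

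The first question was whether the place of a plant in the chamber changed its transcripts. In KP leaf, 404 of 20848 loci changed between the 3 positions. The level of LOC_Os01g17170 on chromosome 1 was 1210 ± 123 CPM (counts relative to the scaled library total) at position A, 427 ± 26.5 at B and 341 ± 92.5 at C (SD, n = 3 each). Its log2 fold change from A to C was -1.83 (SE 0.17; adjusted p = 9.83e-05, edgeR's quasi-likelihood test over the 3 positions with Benjamini-Hochberg adjustment). LOC_Os03g20700 on chromosome 3 went from 3009 ± 480 CPM at A to 1097 ± 43.3 at B and 845 ± 189 at C, with the same log2 change of -1.83 (SE 0.17). In the other direction, LOC_Os10g25060 on chromosome 10 went from 43.8 ± 4.96 CPM at A to 117 ± 22.3 at B and 130 ± 6.35 at C, a log2 change of 1.57 (SE 0.14). LOC_Os02g49230 on chromosome 2 rose from 76.9 ± 6.18 CPM at A to 150 ± 3.28 at C, a log2 change of 0.96 (SE 0.12; adjusted p = 0.00139, edgeR). Position A had the highest mean of the 3 positions for 230 of the 404 loci, the lowest for 122 and lay between the others for 52. The median difference between the highest and lowest position was 1.75-fold, and it exceeded 2-fold for 127 loci.

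The KP leaf count depended on how the spread between libraries was estimated. With a spread shared by all 18 leaf libraries, as planned, 404 loci passed, and with the spread of the 9 KP leaf libraries alone 50 passed. DESeq2's likelihood ratio test called 1614. Leaving out 1 library moved the count by over 1.5 times in 6 of 9 cases: it was 139, 130 and 199 without replicates 1, 2 and 3 of position A, 223 and 629 without replicates 2 and 3 of position B, and 243 without replicate 3 of position C. All 9 KP leaf libraries carried the same library code in their deposited names.

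In IR64 leaf, 320 of the 20848 loci changed between positions. LOC_Os06g24070 on chromosome 6 fell from 134 ± 16.7 CPM at position A to 58.7 ± 4.56 at B and 48.8 ± 4.18 at C (SD, n = 3 each), a log2 change from A to C of -1.46 (SE 0.15; adjusted p = 0.000749, edgeR's quasi-likelihood test). LOC_Os09g36220 on chromosome 9 stood at 638 ± 42.7 CPM at A, 677 ± 34.4 at B and 323 ± 46.7 at C. Position B was the highest for LOC_Os06g39120 on chromosome 6, with 42.3 ± 2.05 CPM against 14.7 ± 2.28 at A and 19.0 ± 3.96 at C. The same held for LOC_Os01g17214 on chromosome 1, with 112 ± 12.9 CPM at B against 43.4 ± 9.85 at A and 48.3 ± 7.43 at C. Position A had the highest mean for 166 of the 320 loci and the lowest for 60. The median difference between the highest and lowest position was 1.69-fold, and 111 loci exceeded 2-fold.

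**Figure D1:**
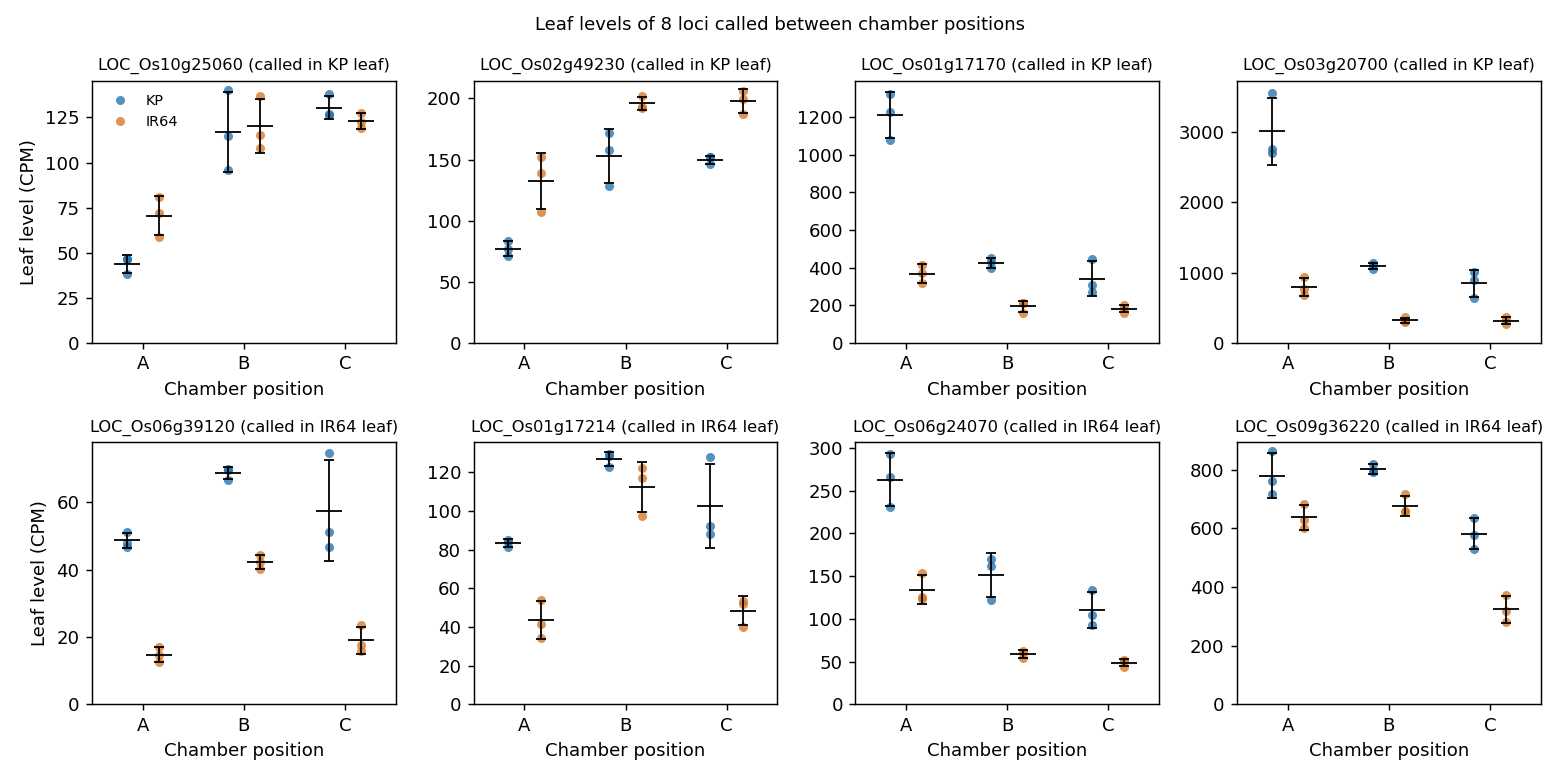
Leaf levels in CPM (vertical axes, from 0) of the 8 loci named for the position comparisons at chamber positions A, B and C (horizontal axes). Each point is 1 library, blue for KP and orange for IR64, and the black marks are the mean and SD of 3 libraries. In KP, LOC_Os03g20700 had 3009 CPM at A and 845 at C, and in IR64, 795 at A and 318 at C.

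With the spread of the 9 IR64 leaf libraries alone 495 loci passed, and DESeq2's likelihood ratio test called 1116. Positions A and B or C of IR64 leaf carried different library codes, while B and C shared 1 code, and 117 loci differed between C and B. Without 1 library the IR64 count was 82, 152 and 177 (replicates 1, 2 and 3 of position A), 137 and 168 (replicates 1 and 3 of B) and 145 and 162 (replicates 1 and 3 of C). Replicate 3 of position A and replicates 1 and 2 of position B stood apart from the other IR64 pools at a few loci, and 52 loci passed without these 3, a count in which position B kept 1 library that was assumed to vary like the other groups. In that fit LOC_Os06g39120 and LOC_Os01g17214 no longer passed (adjusted p = 0.0605 and 0.0736, edgeR; in all alternatives the adjusted p ran from 1.25e-16 and 1.20e-14 up to these values), while LOC_Os06g24070 and LOC_Os09g36220 did. The log2 change from A to B of LOC_Os06g39120 was 1.53 (SE 0.16) with all libraries and 1.45 (SE 0.27) without the 3, and that of LOC_Os01g17214 was 1.37 (SE 0.16) and 1.03 (SE 0.22), so the errors grew with fewer libraries and position B stayed higher than A.

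The position differences of the accessions were correlated in leaf. Of the loci called in KP leaf, 88 were also called in IR64 leaf, where independent lists would share 6.20, and 87 of the 88 had the same direction from A to C. Both lists came from 1 fit with a spread shared per locus, so more than 6.20 can overlap without a common position effect. LOC_Os03g20700, named for KP, averaged 795 ± 128 CPM at A and 318 ± 48.7 at C in IR64 leaf, and LOC_Os10g25060 averaged 70.5 ± 10.96 and 123 ± 4.36 (SD, n = 3 each). Across 11113 loci with a mean log2 CPM of at least 3, the position means of KP and IR64, centred per accession, had a correlation of 0.578 in leaf and -0.0681 across 12519 loci in root tip. Loci are not independent replicates, so the position labels of the IR64 libraries were permuted: 2 of the 1680 relabelings gave a leaf correlation as large, the real one included (exact p = 0.00119, one-sided, adjusted p = 0.00238 over both tissues), and 1175 of 1680 did in root tip (exact p = 0.699). A position effect that differed between the accessions was called in leaf for 0 loci by edgeR and by limma-voom and for 21 by DESeq2. An unadjusted p under 0.05 was reached by 1221 of 20848 loci, where chance gives 1042.

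**Figure D2:**
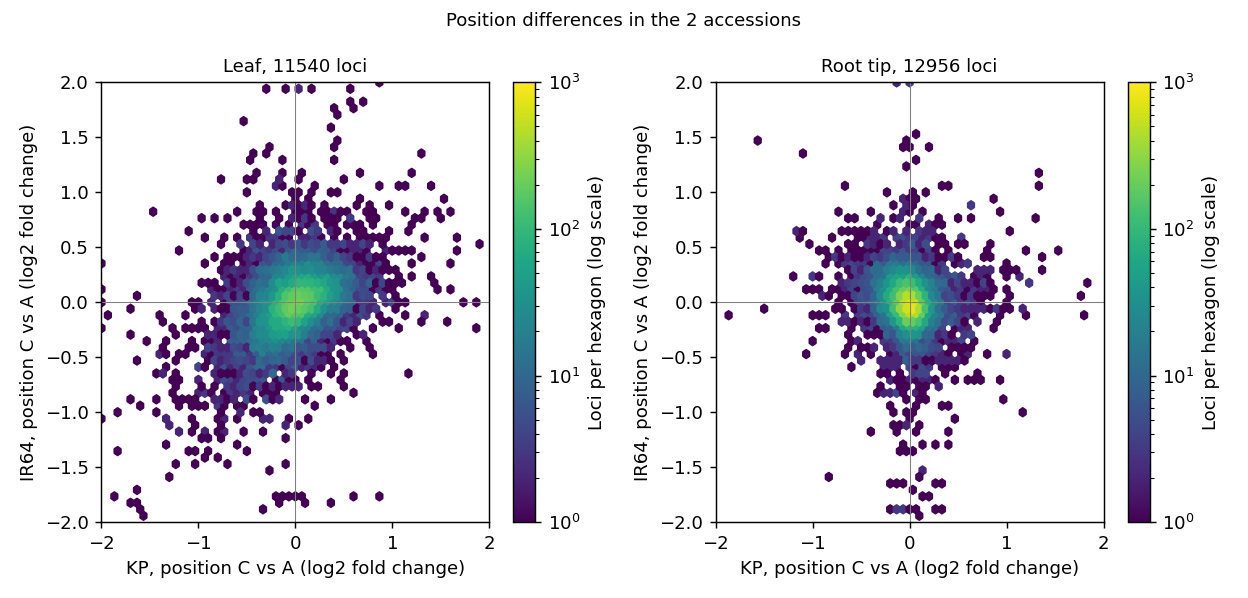
Log2 fold change from position A to C in KP (horizontal axes) against IR64 (vertical axes) for 11540 loci in leaf and 12956 in root tip with an average log2 CPM of at least 3, drawn between -2 and 2, with 53 and 48 loci outside. Colour gives the number of loci per hexagon on a log scale. The leaf cloud runs from lower left to upper right and the root tip cloud has no such slope, with correlations of the C to A differences of 0.513 and -0.141 across 11113 and 12519 loci.

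In root tip, 0 of 21816 loci changed between positions in either accession (edgeR's quasi-likelihood test). At an unadjusted p under 0.05 there were 780 loci in KP and 2110 in IR64, where chance gives 1091. The fit shared 1 spread, while the median replicate SD of log2 CPM was 0.0944 in KP root tip and 0.141 in IR64 root tip. A shared spread can make p-values too large in KP and too small in IR64, so no position effect is read from these counts. In IR64 the median SD of the position means was 0.0762, against 0.0816 from the replicates alone, and in KP it was 0.0561 against 0.0545. The smallest adjusted p was 0.964 in KP and 0.335 in IR64. limma-voom also called 0 in each, and DESeq2's likelihood ratio test called 29 in KP and 98 in IR64. Without replicate 1 or replicate 3 of position C in IR64 root tip, edgeR called 3 and 2 loci. The accession difference of the position effect was called for 0 loci with edgeR and limma-voom and for 27 with DESeq2, with 1474 loci at an unadjusted p under 0.05. It was called for 2 loci without replicate 1 of position C in IR64 root tip.

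A count of 0 does not show equal levels, so the intervals of the differences were counted too. The 95% intervals of all 3 pairwise log2 fold changes lay inside -1 to 1 for 73.5% of the loci tested in KP root tip (jackknife SE 0.891 percentage points over 9 libraries) and 70.0% in IR64 root tip (SE 1.58). In leaf the shares were 65.3% in KP (SE 2.44) and 66.2% in IR64 (SE 2.93). The intervals used the spread shared by both accessions, so they can be too wide in KP root tip and too narrow in IR64 root tip. All shares with 1 library left out lay below the full value (70.3% to 71.3% in KP root tip), a shift that the jackknife SE does not cover. In simulated counts with these spreads, 2-fold changes at 1 position were recovered for 58.2% of 67 loci in KP leaf, 53.7% in IR64 leaf, 62.7% in KP root tip and 68.7% in IR64 root tip, the last in a fit in which 37.5% of calls were false. With the spread of the 9 libraries of an accession and tissue alone, the recovered shares were 47.8%, 53.7%, 73.1% and 44.8%. The simulated loci varied independently of each other, which the real loci did not, so these shares may not hold for the data. A test of whether the position effect differed between leaf and root tip, added after the counts were seen, called 57 of 24404 loci in KP and 38 in IR64. Of the leaf position calls, 44 of 404 in KP and 35 of 320 in IR64 passed it.

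The accessions differed at many expressed loci. In leaf, 13052 of 20848 loci differed between IR64 and KP over the 3 positions, 6518 higher and 6534 lower in IR64, and 4592 of them by at least 2-fold (2049 higher, 2543 lower). LOC_Os09g39060 on chromosome 9 averaged 234 ± 78.1 CPM in IR64 leaf and 3.01 ± 0.867 in KP leaf (SD, n = 9 each), a log2 fold change of 6.26 (SE 0.15; adjusted p = 5.00e-14, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). LOC_Os02g17292 on chromosome 2 averaged 59.0 ± 6.52 CPM in IR64 and 1.17 ± 0.442 in KP, a log2 change of 5.69 (SE 0.14). LOC_Os11g14544 on chromosome 11 averaged 0.330 ± 0.223 CPM in IR64 and 273 ± 21.3 in KP, a log2 change of -9.79 (SE 0.19). LOC_Os01g71630 on chromosome 1 averaged 0.349 ± 1.02 CPM in IR64 and 537 ± 63.7 in KP (adjusted p = 8.48e-09, edgeR). Of its 67 counts in IR64 leaf 65 were in replicate 3 of position B, and position A had none, so no log2 change is given.

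In root tip, 12284 of 21816 loci differed, 6229 higher and 6055 lower in IR64, and 4017 by at least 2-fold, 1993 of these higher in IR64. LOC_Os02g46260 on chromosome 2 averaged 394 ± 26.1 CPM in IR64 root tip and 0.676 ± 0.233 in KP root tip (SD, n = 9 each), a log2 change of 9.18 (SE 0.12; adjusted p = 1.19e-18, edgeR). LOC_Os11g15180 on chromosome 11 averaged 273 ± 98.2 CPM in IR64 and 8.03 ± 3.78 in KP, a log2 change of 5.12 (SE 0.23). LOC_Os01g71630 was lower in IR64 here too, with 0.320 ± 0.136 CPM against 412 ± 27.2 in KP (log2 change -10.30, SE 0.19). LOC_Os10g40520 on chromosome 10 averaged 1.07 ± 0.266 CPM in IR64 and 229 ± 45.1 in KP, a log2 change of -7.75 (SE 0.14).

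Some loci had reads in 1 accession only. At no more than 3 counts over the 9 libraries of one accession and at least 1 CPM in each library of the other, 256 loci were read only in KP leaf (1.59% of the 16055 loci with at least 1 CPM in every KP leaf library) and 197 only in IR64 leaf (1.22% of 16117). In root tip there were 318 (1.82% of 17445) and 178 (1.05% of 16978). These criteria were met in both tissues by 149 loci for KP and 91 for IR64, and no locus was read only in KP in one tissue and only in IR64 in the other. Among all loci tested, whether called or not, every IR64 library lay above or below every KP library for 5179 in leaf (24.8%) and 5050 in root tip (23.1%), where chance gives 0.00411% of loci.

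The accession differences were shared in part between the tissues. Of 18356 loci tested in both, 6847 were called in both, where independent lists would share 6246. The direction was the same for 5253 of these (76.7%) and opposite for 1594. Leaf and root tip came from separate libraries, and the correlation of the log2 differences across loci was 0.810. Of the loci that differed by at least 2-fold in both tissues, 166 of 1729 went in opposite directions.

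**Figure D3:**
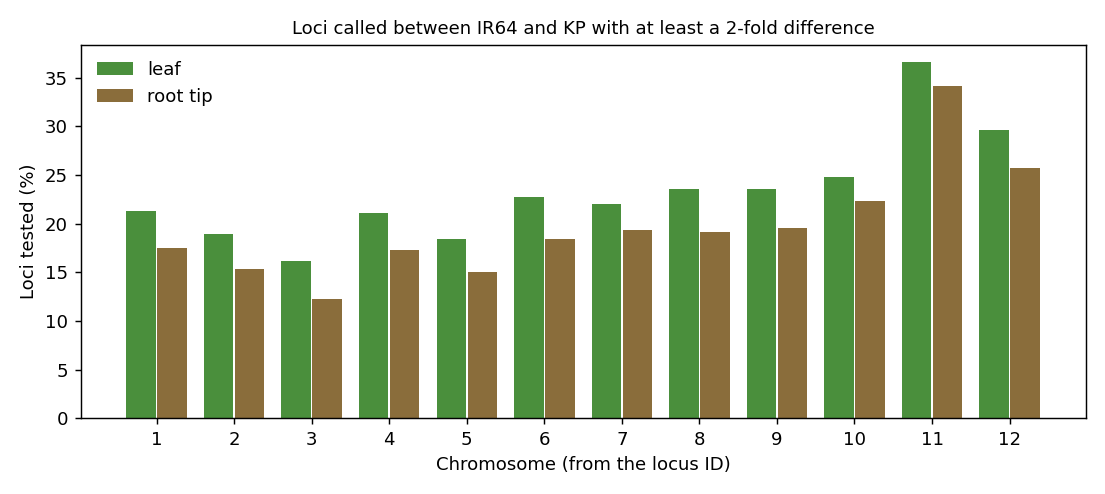
Share of the loci tested on each of the 12 chromosomes (horizontal axis) that differed between IR64 and KP with at least a 2-fold change, in percent (vertical axis, from 0), green for leaf and brown for root tip. Chromosome 11 had the highest bars, 36.6% in leaf and 34.2% in root tip, and chromosome 3 the lowest, 16.2% and 12.2%.

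Loci that differed by at least 2-fold made up 22.0% of the loci tested in leaf and 18.4% in root tip, and their share varied along the genome. It was 36.6% on chromosome 11 and 29.6% on chromosome 12 in leaf, against 16.2% on chromosome 3, and 34.2%, 25.7% and 12.2% in root tip. Shifting the calls along the genome 10000 times gave a range between chromosomes as large in a share of 0.071 in leaf and 0.12 in root tip. Each shift kept dense stretches of calls whole and could repeat much of the range. The test therefore does not settle whether the range exceeds what clustered calls give. In windows of 50 neighbouring tested loci the share ran from 0% to 58% in leaf and from 0% to 76% in root tip, with an SD of 10.4 percentage points in leaf where independent loci would give 5.86, and 10.1 against 5.48 in root tip.

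Accession and library code overlapped in part. Within position A, whose 6 leaf libraries carried 1 code, 10354 loci differed between the accessions in leaf, and within position C, whose 6 root tip libraries carried 1 code, 8025 differed in root tip. A model with the code as a term called 9719 of 20848 loci in leaf and 8605 of 21816 in root tip, fewer than the 13052 and 12284 called without it. The counts rest on reads aligned to 1 reference genome, so a lower count can reflect a lower transcript level or a sequence that aligns less well, and the counts alone do not separate these.

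Leaf and root tip differed at most loci tested. In KP, 21957 of 24404 loci differed, 11173 higher and 10784 lower in root tip, and 16627 by at least 2-fold. In IR64, 21585 differed, 11104 higher and 10481 lower, and 16374 by at least 2-fold. LOC_Os02g47420 on chromosome 2 averaged 117 ± 10.1 CPM in KP root tip and 1.76 ± 0.396 in KP leaf (SD, n = 9 each), a log2 change of 6.08 (SE 0.08; adjusted p = 1.30e-31, edgeR's quasi-likelihood test). LOC_Os11g25920 on chromosome 11 was named in both accessions, with log2 changes of 5.11 (SE 0.06) in KP and 4.99 (SE 0.06) in IR64. In IR64, LOC_Os06g22100 on chromosome 6 averaged 48.7 ± 3.49 CPM in root tip and 0.0634 ± 0.0635 in leaf, a log2 change of 9.89 (SE 0.37). LOC_Os02g01340 on chromosome 2 averaged 2433 ± 115 CPM in KP leaf and 2181 ± 210 in IR64 leaf, with 16 counts over the 9 KP root tip libraries and 12 over the 9 IR64 ones. LOC_Os08g27150 on chromosome 8 averaged 164 ± 9.87 CPM in KP leaf and 2.44 ± 0.156 in KP root tip (log2 change -6.06, SE 0.05), and 135 ± 11.8 and 2.72 ± 0.250 in IR64 (log2 change -5.63, SE 0.05).

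The leaf and root tip libraries of an accession shared no library code, but IR64 leaf positions B and C and KP root tip positions A and B carried 1 code. A model with the code as a term and 1 tissue effect for both accessions, added after the results were seen, called 18865 of 24404 loci. Of the 19151 loci called in both accessions in the same direction, it called 94.3%, all in that direction. Within the code that held both tissues, accession changed together with tissue, so this model assumes an equal accession difference in both tissues. That did not hold for the 9635 loci given below, so the model does not exclude the code for the tissue calls. The tissue contrast was largely common to the accessions. Both accessions called 19920 loci, 96.1% of them in the same direction and 769 in opposite directions, and the log2 changes had a correlation of 0.907 across loci. At 1 CPM or more in every library of one tissue and at most 3 counts over the 18 libraries of the other, 214 loci were read in leaf alone and 422 in root tip alone. The difference between the accessions was itself different in leaf and root tip for 9635 of 24404 loci, with the IR64 to KP ratio higher in root tip for 5554 and lower for 4081. The library codes were spread unevenly over accessions and tissues, and a model with the code as a term, added after the results were seen, called 5856 loci, 5379 of them among the 9635 and all of these in the same direction.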

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

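The position by tissue test, the fit with the library code, the groupings with the spread of 9 libraries and all tests of explanations in this part were chosen after the results were seen, while the rule for counting other groupings of the libraries was set before the counts from those groupings were seen, except for KP leaf with the shared spread.

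The difference between IR64 and KP differed between leaf and root tip for 9635 loci by an interaction term. In none of 23 other groupings did more than 1 locus pass (1 of 24 groupings, the real one included, reached the count). Those groupings mixed the 2 accessions within groups, so the difference between accessions itself widened their spread. Their low counts therefore decide nothing about the interaction. With the library code as a term 5856 passed, 5379 of them among the 9635. The accessions shared a code only at position A in leaf and position C in root tip. Fewer calls can thus come from fewer informative libraries or from the codes, and the cause was not tested. Among the loci named for the comparisons, the log2 difference of the IR64 to KP change, root tip minus leaf, was 8.88 for LOC_Os02g46260, 4.23 for LOC_Os11g14544, 3.37 for LOC_Os01g71630, 3.23 for LOC_Os02g17292, 2.19 for LOC_Os06g22100, 0.43 for LOC_Os08g27150 and -1.05 for LOC_Os02g47420. The value of LOC_Os06g22100 rests on few leaf counts, 36 over the 9 KP libraries and 11 over the 9 IR64 ones. Its root tip levels were 47.3 ± 1.84 CPM in KP and 48.7 ± 3.49 in IR64. Scaled over all 36 libraries, LOC_Os02g46260 averaged 58.7 ± 8.64 CPM in IR64 leaf and 318 ± 21.5 in IR64 root tip, and 47.8 ± 25.9 and 0.534 ± 0.188 in KP (SD, n = 9 each). The value of LOC_Os01g71630 comes from a fit in which IR64 leaf position A had no count. Its levels were 672 ± 81.5 CPM in KP leaf and 0.436 ± 1.27 in IR64 leaf (67 counts, 65 of them in 1 library), and 325 ± 22.2 and 0.258 ± 0.109 in root tip, so no difference between the tissues is read from it.

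The position effect differed between leaf and root tip for 57 loci in KP and 38 in IR64 by an interaction term. The leaf effect was the pattern weighed first. In KP leaf 404 loci passed, and 2 of 60 groupings of the 9 libraries, the real one included, gave as many, with 477 the highest other. With the spread of the 9 KP leaf libraries alone 50 passed, and again 2 of 60 gave as many, with 342 the highest other. The share of 2 of 60 lies under 0.05 with either spread. The groupings were a sample of those possible, however, and another one called more each time, so chance was not excluded in KP leaf. A grouping that called several times as many points to a structure of the KP leaf libraries that does not follow position. In IR64 leaf 320 passed and the highest of 59 other groupings called 46 (1 of 60), and with its own spread 495 passed against 22 (1 of 60). The groupings were a sample here too, and 1 of 60 is the smallest share they allow. Chance is thus unlikely in IR64 leaf, at that resolution. Several technical sources were set against a real effect of position. A library code was excluded for KP, where the 404 calls arose within 1 code, and for positions B and C of IR64, where 117 loci differed within 1 code. Position A of IR64 leaf carried another code than B and C and cannot be told apart from it there, although the IR64 difference from A to B had a correlation of 0.605 with that of KP, where the code did not change. Depth was excluded by 396 calls in KP and 325 in IR64 at equal depth, and a few abundant loci by 387 and 295 calls without the 50 largest. Chance in KP leaf stays open. So do the position itself, the order or time at which plants were sampled, which the labels do not give, and any handling that followed position in both accessions. A direction of variation that also separated replicates in leaf stays open too, so a position effect in leaf remains a hypothesis.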

How the results depend on the processing

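Named loci kept their direction in the 527 comparisons made: 525 kept their side of the threshold and 2 lost it, both without the 3 IR64 pools. They were not followed at equal depth or without the top loci, and DESeq2 gave an adjusted p for 23 of 24. They had been chosen as the most extreme loci of the same data, so this stability was largely set by the choice. For position loci the direction was that of C against A. In LOC_Os06g39120 and LOC_Os01g17214, highest at B, that log2 change was 0.37 (SE 0.16) and 0.16 (SE 0.16), so its direction says little about them. Chosen after the data were seen were the fit without the 3 IR64 pools, equal depth, the removal of the top loci and models with the library code. These models called 18865 loci for tissue and 5856 for the tissue by accession difference, where codes and groups overlap and the cause was not tested. DESeq2 moved every position count, to 1614 in KP leaf, 1116 in IR64 leaf, 29 in KP root tip and 98 in IR64 root tip, and to 21 and 27 for the accession difference of the position effect in leaf and root tip. With only the 9 libraries of an accession and tissue, 50 loci passed in KP leaf and 495 in IR64 leaf, against 404 and 320; simulated spreads that differed between accessions gave unequal false calls, and the cause was not tested further. Without the 3 IR64 pools, 52 loci passed in IR64 leaf and 9 for the accession difference of the leaf position effect; 1 library was then left at position B, and fewer samples entered. Leaving out 1 library gave 130 to 629 loci in KP leaf, 82 to 361 in IR64 leaf, 0 to 3 in IR64 root tip and 0 to 2 for the accession difference in root tip, and 0 in every case for KP root tip and for the accession difference in leaf. Asking for at least a 2-fold change left 4592 loci between accessions in leaf, 4017 in root tip and 4009 for the tissue by accession difference. Within position C alone, with 6 libraries, 8025 loci differed between accessions in root tip against 12284. The other accession and tissue counts stayed within 1.5 times.

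The shares of loci with intervals inside the bounds fell with a 1.5-fold bound to 38.3% in KP leaf, 40.7% in IR64 leaf, 57.0% in KP root tip and 52.9% in IR64 root tip, as a narrower bound must. Without the expression filter they were 40.3%, 40.9%, 48.3% and 46.1%, since loci with few counts have wide intervals. Leaving out 1 library gave 61.0% to 64.1%, 61.8% to 65.3%, 70.3% to 71.3% and 66.9% to 68.7%, with fewer samples.

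The counts did not show that replicate numbers pair the libraries: deviations of libraries with the same number from their group means had median correlations of -0.0121 within leaf, -0.0132 within root tip and 0.0186 between the tissues, and 3 of 18 libraries correlated best with their own number in the other tissue. Since 4 loci were read in the same 3 IR64 pools in both tissues, IR64 leaf and root tip libraries of 1 number may still come from the same plants. With a replicate block, 334 loci passed in KP leaf, 241 in IR64 leaf and 0 in both root tips and both accession differences of position. Between accessions 12951 passed in leaf and 11953 in root tip, between tissues 21849 in KP and 21506 in IR64, and 8781 for the tissue by accession difference. The gene list tests and the named root and stature genes were not run, since no ID could be matched to a name. The counts of 0 in root tip leave 2-fold position changes possible, since in simulated counts 62.7% of these were recovered in KP and 68.7% in IR64 with a shared spread, and 73.1% and 44.8% with the 9 libraries alone. At equal depth 396 loci passed in KP leaf and 325 in IR64 leaf; root tip was thinned for the replicate spread and not for its position counts.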

Other observations

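All tests in this part that explain a pattern were chosen after the pattern was seen, and the levels in the 3 pools and the groupings with the spread of 9 libraries were added after the other results.

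A few loci had at least 1 CPM in 3 of the 9 IR64 pools and at most 2 counts in each of the others (3 over all of these), with at least 1 CPM in every KP library of the tissue. Of these, 4 loci in leaf and 5 in root tip, with 4 in common, shared the same 3 pools (the other, LOC_Os09g26554, had 4 counts in leaf replicate 3 of position B). The 3 pools were replicate 3 of position A and replicates 1 and 2 of position B. LOC_Os09g26554 on chromosome 9, chosen after its values were seen, had 33.2, 37.7 and 39.6 CPM in these root tip pools (863, 865 and 915 counts) and no count in the other 6, against 67.9 ± 3.52 in KP root tip (SD, n = 9). LOC_Os12g15222 on chromosome 12 had 21.9, 29.2 and 31.8 CPM in leaf, at most 1 count in any other IR64 leaf pool, and 91.4 ± 7.70 in KP leaf. The 5 loci lay on chromosomes 1, 3, 9 and 12. Among other sets of 2 to 7 IR64 pools, 1 locus was read in root tip replicate 3 of position A, replicate 3 of position B and replicate 2 of position C. No other set of 2 to 7 IR64 pools had more than 1 such locus, and no set of 2 to 7 KP pools had any. Outside this range, 2 loci were read in IR64 leaf replicate 3 of position B alone, and 1 locus in 8 of the 9 KP leaf pools. In that IR64 leaf library, loci otherwise read in KP alone stood at 0.331% of their KP level, against 0.0214% to 0.0378% in the other 8. KP RNA or reads carried into the pools at the levels of the 5 loci do not account for this. That would leave few loci read in KP alone, with at most 3 counts over the 9 IR64 libraries. There were 256 in leaf and 318 in root tip. A swap with KP does not either, since it would leave few loci read in IR64 alone, and there were 197 and 178. In the 3 pools, other loci read in KP alone stayed at or below 0.0416% of their KP level. Loci read in IR64 alone stayed at or above 91.2% of their IR64 mean, and the choice of loci can set both levels. The return of the same 3 pools in both tissues, for 4 loci, is consistent with plants of another genotype at these loci in these pools, which is a hypothesis. The levels there ran from 20.6% to 120% of the KP level, and 25 of 30 values lay above the 33.3% that 1 of 3 pooled plants makes up. A single plant at the KP level therefore does not account for the levels, and neither the number of such plants nor their own level is known.

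IR64 root tip libraries differed more from each other than those of KP. The mean spread of pairwise log2 differences was 0.330 ± 0.0570 in IR64 and 0.202 ± 0.0275 in KP (SD, n = 3 positions each; exact permutation p = 0.1, two-sided, the smallest this design allows). Depth did not account for it, since the ratio of the median replicate SD of IR64 to KP was 1.45 at equal depth. Leaf markers reached at most 0.104% of their leaf level in any root tip library, in IR64 replicate 3 of position A, and at most 0.0408% in KP. The 100 markers were chosen from these libraries by a leaf minimum over 100 times the root tip median. Their usual level in root tip was thus low by choice, and only a library standing apart could show. More leaf tissue than this in single root tip libraries was not seen, while carry-over common to the tips could not be tested. The 3 pools above are not the whole of it, since position C, which holds none of them, had a spread of 0.306 against a KP maximum of 0.231. Differences between plants or in where the tips were cut could add spread and were not tested.

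Other groupings of the 9 IR64 root tip libraries called up to 1800 loci, and 10 of 59 called over 100, against 0 for the real positions (60 of 60 groupings reached that count). With the spread of the 9 IR64 root tip libraries alone the highest other grouping called 259 and no further one over 100, against 0 for the real positions, so many of these calls came with the spread shared with KP. Whether the rest reflects a structure of the libraries cannot be told apart from that spread, since 259 lies between the bounds set for either. KP root tip had at most 2 calls in other groupings (60 of 60), and the accession difference of the position effect at most 9 in leaf and 31 in root tip (60 of 60 each). A count of 0 is reached by every grouping, so these comparisons decide nothing about the root tip positions or the accession difference. The accession counts were 13052 in leaf against 9820 for the highest other grouping and 12284 in root tip against 8958 (1 of 60 groupings each). The tissue counts were 21957 in KP against 17589 and 21585 in IR64 against 17734 (1 of 24 each). Those other groupings mixed the accessions or the tissues within groups, so the difference tested itself widened their spread. Their counts therefore do not show what chance alone gives.

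In leaf, the main direction in which replicates of a group deviated from their mean took 52.6% of that deviation in KP and 63.2% in IR64, and the loadings of the 2 accessions had an absolute correlation of 0.591 across 11113 loci, against 0.0796 in root tip. In leaf this direction in IR64 also correlated with the position differences of KP (absolute values 0.311 for B against A, 0.0358 for C against A and 0.308 for C against B), and that in KP with the position differences of IR64 (0.146, 0.268 and 0.406). Loci are not independent replicates and these values have no p.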
